A study of Mus musculus with 6 samples.

How the data were processed

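RNA from 6 mouse samples was measured on Affymetrix Mouse Gene 2.0 ST arrays, with 1 array per sample and 1 sample per group. Per the labels' protocols, RNA was extracted with TRIzol and purified on columns, and labelled sense cDNA was made from 300 ng of total RNA. The groups, taken from the sample titles, were undifferentiated iPS cells, iPS cells at day 7 with DMSO, with NRG-1 or with both, neonatal cardiomyocytes and adult cardiomyocytes. The deposited table holds log2 expression values of 41345 probe sets, which the authors made with RMA, per the submitters' processing notes. RMA corrects background, equalises the distributions of the arrays and summarises the probes of a probe set. Its version and software are not given in the sources used here. The log2 scale was read from the values. The sorted values of the 6 columns differed by at most 0.285, so a change in total RNA or in most genes at once could not be seen. The table has no background or detection values, so signal over background could not be judged probe by probe.

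Probe sets were named through the platform annotation. It lists 25335 of them, 23521 with 1 gene symbol and 1814 with several, and 16010 probe sets are unnamed here. Of those with 1 symbol, 23328 had an Entrez identifier in the RefSeq table of assembly GRCm38, which changed no symbol. No gene was named from a probe set with several symbols, and no coordinates are given because the table names no genome build. The value of a gene was the mean over its probe sets, which gave 22180 genes, 1082 of them with more than 1 probe set.

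Because each group has 1 library, no test was run and no p-value is given. The 9 comparisons are differences of log2 values. A gene entered a count if the higher of its 2 values was at or above the median of all values (5.20), and genes at least 2-fold or 4-fold apart were counted. The only measure of technical error was the disagreement of 2 probe sets of 1 gene, the SD of the difference between their log2 differences divided by the square root of 2, over 449 to 509 genes. It mixes noise with true differences between transcripts. The number of arrays limits the precision of all values. The choices of comparisons, filter, fold thresholds, gene lists and named genes were made before the data were examined.

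There were 31 gene lists, of which 439 of 477 entries were measured: pluripotency, mesendoderm and early mesoderm, cardiac transcription factors, cardiac sarcomere, ventricular, atrial, pacemaker and conduction, calcium handling and ion channels, fetal heart isoforms, adult heart isoforms, fatty acid oxidation, oxidative phosphorylation, glycolysis, cell cycle, ERBB receptors and ligands, ERK feedback and immediate response, fibroblast and matrix, endothelial, smooth muscle, macrophage and leukocyte, erythroid, adipocyte, neural, endoderm, skeletal muscle, epithelial, epicardial and mesothelial, imprinted growth genes, dissociation stress, sex-linked and housekeeping. Lists share some members. For each list the median difference of all measured members was set among 10000 random lists of the same size, drawn in 20 bins of mean expression over the 6 libraries. Members below the filter in both libraries are called dim and enter the median but not the counts of genes 2-fold apart. The text names the 12 genes with the largest differences each way among genes that passed the filter, leaving out predicted, clone, microRNA, small RNA, receptor segment, olfactory, vomeronasal and histone names by their prefixes. The small RNA genes Rny3, Rprl2 and Rpph1 and the histone H2ac1 have other prefixes and were kept. It also names up to 4 members of each list with the largest differences, any member of the sarcomere, ventricular, atrial, cardiac transcription factor, pluripotency and ERBB lists, and all sex-linked genes. A few further members are given as examples of known markers and were chosen after their values were seen.

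Alternatives were no filter on dim genes, a filter at the 75th percentile of all values (6.93), the brightest probe set of a gene, cyclic loess between the arrays, and a shift of each library to an equal median of 11 measured housekeeping genes. This housekeeping shift makes the median level of these genes equal, not the differences of the single genes. List medians were also taken over members that passed the filter and over members on no other list. After the data were seen, list medians and single genes under the housekeeping shift were given relative to the median of all genes, because that shift moved the median by up to 1.05. A value was called moved when it differed by 1.5-fold or more (0.58 on the log2 scale, or 0.05 for a correlation).

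The counting and list steps were tested on simulated data for the 22180 genes, with noise set to the probe set disagreement of each comparison and 200 genes made different. For NRG-1 minus DMSO, 95.5% of genes set 2.83-fold apart and 100% of genes set 8-fold apart were counted in the right direction, beside 14 and 18 unchanged genes. For neonatal minus iPS the same sizes gave 77.5% and 100%, beside 1347 and 1329 unchanged genes. The noise was set to 0.589 there and to 0.305 for NRG-1 minus DMSO. Because that measure mixes noise with true differences between transcripts, how many genes counted against the iPS library come from noise cannot be told. Of 200 random lists with no shift, 4% fell outside the central 95% of the random lists. The genes were simulated as independent, so this does not show how medians of genes that change together would spread. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used, and R 4.3.3 with limma 3.58.1 for cyclic loess.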

Results

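Gene expression was measured on Affymetrix Mouse Gene 2.0 ST arrays in 6 mouse RNA libraries, each the single library of its group. Mouse induced pluripotent stem (iPS) cells, which are reprogrammed cells able to form most cell types, gave 1 undifferentiated library. Another 3 libraries came from iPS cells at day 7 of cardiac differentiation, after 5 days as embryoid bodies in suspension and then plating with 1% DMSO, with 100 ng/ml NRG-1, or with both. DMSO is a solvent also used to start differentiation, and NRG-1 (neuregulin 1) is a growth factor that signals through ERBB receptors. The remaining libraries were labelled neonatal cardiomyocytes and adult cardiomyocytes, and all names used here are those of the labels. The table held 41345 probe sets. The 25th, 50th and 75th percentiles of the iPS library were 3.87, 5.13 and 6.91 on the log2 scale, and the medians of the others lay between 5.15 and 5.26. With 1 library per group, no difference given here has a replicate check and none was tested. Each value is a difference of log2 values between 2 libraries, and the number of arrays limits the precision. The percentile given for a gene list places its median among 10000 random lists matched on expression, as a description of these libraries.

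Sex-linked genes were read first as a check of the labels, which give every sample as female. In the adult library the Y-linked genes stood at 8.15 for Eif2s3y, 7.02 for Kdm5d and 7.55 for Uty, against 3.27, 3.08 and 4.06 in the iPS library. Xist, the RNA that coats the inactive X chromosome, was 3.39 in the adult library and 5.97 in the iPS library. The neonatal library had Xist at 8.78 together with Eif2s3y at 6.20, Kdm5d at 6.17 and Uty at 7.14. In the libraries with DMSO, NRG-1 and both, Xist was 6.49, 6.91 and 6.87, and the highest value of a Y-linked gene was 3.65, for Uty with DMSO. The Y-linked values of the adult and neonatal libraries go against their labels as female. Over the 4 measured sex-linked genes the list median was 3.72 for adult minus iPS (percentile 100) and 3.0 for neonatal minus iPS (percentile 100).

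**Figure D1:**
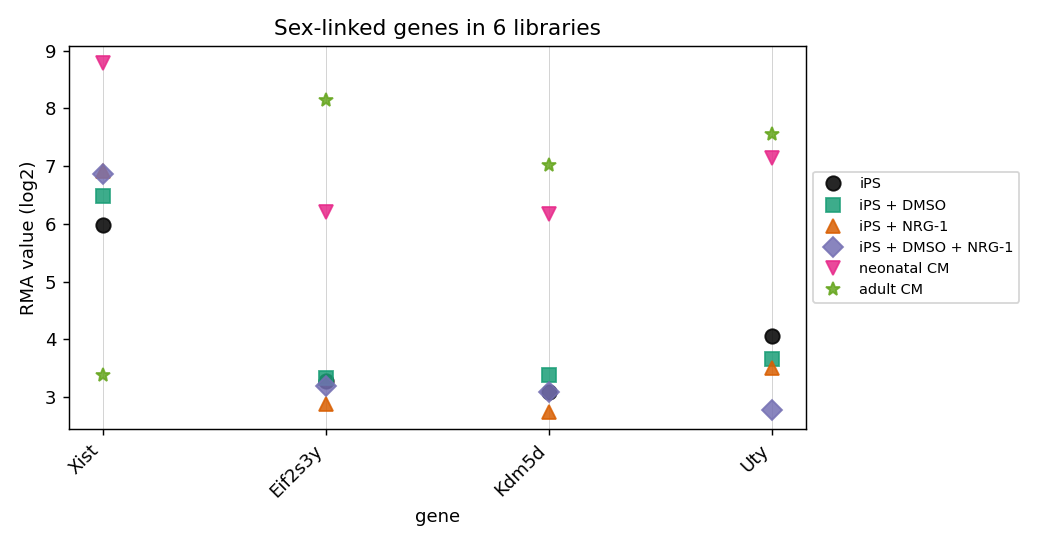
Each point is the RMA value (log2, vertical axis) of 1 sex-linked gene (horizontal axis) in 1 of the 6 libraries, named in the key. Eif2s3y, Kdm5d and Uty were at 6.17 or above in the neonatal and adult cardiomyocyte (CM) libraries and at 4.06 or below in the iPS and treated iPS libraries, and Xist was lowest in the adult library, at 3.39.

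The neonatal cardiomyocyte library was set against undifferentiated iPS cells to describe the expression of heart-derived cells. Genes of the pluripotent state were far lower in it, and connective tissue genes were far higher. Nanog, a core pluripotency factor, differed by -7.25, Sox2 by -6.88 and Tdgf1, a co-receptor for Nodal, by -8.10. All 16 measured fibroblast and matrix genes were at least 2-fold higher, including the collagens Col1a1 (4.38) and Col3a1 (4.56) and the collagen receptor Ddr2 (4.42). Of the 27 measured sarcomere genes, 5 were at least 2-fold higher and 0 lower.

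Of the 23 pluripotency genes, 21 were at least 2-fold lower in the neonatal library, with a list median of -3.85 (percentile 0). Cell cycle genes had a median of -0.66 (percentile 0), 6 being lower and 2 higher, and the median was 0.21 under a shift to equal housekeeping medians. The fibroblast and matrix median was 3.77 (percentile 100) and the smooth muscle median 1.85 (percentile 99.99), with Acta2, smooth muscle actin, at 2.53 and the calponin Cnn1 at 2.22. The sarcomere list median was 0.61 (percentile 100). Within it, cardiac troponin T (Tnnt2) differed by 3.42, cardiac actin (Actc1) by 1.45 and tropomyosin 1 (Tpm1) by 2.38, while the myosin heavy chains Myh6 and Myh7 differed by 0.65 and 0.52 and the ventricular light chain Myl2 by 0.61. Cardiac transcription factors had a median of 0.94 (percentile 99.98). Tbx20 was higher by 4.46, Hand2 by 2.24, Gata4 by 2.23 and Hey2 by 2.22, whereas Nkx2-5 differed by -0.22. The ventricular, atrial and fetal isoform medians were 0.34, 0.59 and 0.60 (percentiles 96.3, 99.94 and 99.3), Nppa, the atrial natriuretic peptide, being higher by 5.02. The fetal isoform median was -0.65 over the 4 members on no other list. The adult isoform median was 0.20 (percentile 97.1). Among calcium handling genes, with a median of 0.24 (percentile 98.1), Pln, the regulator of the calcium pump, was higher by 2.80, and Slc8a1, the sodium-calcium exchanger, by 2.44. Under the housekeeping shift the sarcomere, ventricular and atrial medians were 1.48, 1.21 and 1.46. The fetal isoform, adult isoform and calcium handling medians were then 1.46, 1.07 and 1.11. Epicardial and mesothelial genes had a median of 1.05 (percentile 99.9), with Tcf21 at 3.95 and Tbx18 at 3.42. Of the 11 epithelial genes, 6 were at least 2-fold lower and 2 higher, with a median of -1.46 (percentile 0). Epcam, an epithelial adhesion molecule, differed by -4.41, and the keratins Krt18 and Krt19 by 2.19 and 1.52.

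Among the largest positive differences outside the lists were those of Gucy1a1 and Gucy1b1, the subunits of soluble guanylate cyclase (7.15 and 6.19), Esm1 (6.93), the matrix proteoglycan Ogn (6.82), Spon2 (6.64) and the mechanosensitive channel Piezo2 (5.30). In all, 1759 of 13582 genes were at least 2-fold higher and 1524 lower, and 612 and 425 were at least 4-fold higher and lower. With every library shifted to an equal median of the 11 housekeeping genes, which moved the median of all genes by 0.82, the counts were 5490 higher and 450 lower. The median difference of the housekeeping genes themselves was -0.42 as deposited and 0.45 under that shift. Over all comparisons that shift changed the sign of 75 of 279 list medians. The SD of the differences was 1.12, and probe sets of 1 gene disagreed with an SD of 0.589.

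The adult cardiomyocyte library was compared with iPS cells in the same way. Connective tissue genes were again much higher and pluripotency genes much lower, and the sarcomere list stood near the level of the iPS library in the values as deposited. The 16 fibroblast and matrix genes were all at least 2-fold higher, with a median of 4.44 (percentile 100). Only 3 of 27 sarcomere genes were at least 2-fold higher, 1 was lower, and the list median was 0.03 (percentile 66.5), or 0.86 under the housekeeping shift, which moved the median of all genes by 0.82. The adult-type myosin heavy chain Myh6 differed by -0.77, and Myl2, troponin I (Tnni3), creatine kinase (Ckm) and myoglobin (Mb) differed by 0.39, -0.29, 0.29 and 0.14.

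Within the fibroblast and matrix list, the matricellular gene Postn was higher by 4.70, Dcn (decorin) by 4.79, Fbln2 by 4.74, the crosslinking enzyme Lox by 4.76 and the receptor Pdgfrb by 4.44. Smooth muscle genes had a median of 1.62 (percentile 100), or 2.40 without dim members, Tagln being higher by 3.49, and macrophage and leukocyte genes one of 1.23 (percentile 100), Lyz2 (lysozyme) being higher by 3.96. The sarcomere genes at least 2-fold higher were Tnnt2 (1.87), Tpm1 (2.23) and Cryab (2.09), and the desmin gene Des differed by -1.29. Medians of the adult isoform, fetal isoform, ventricular, atrial and calcium handling lists were 0.16, -0.20, 0.15, 0.38 and 0.06, at percentiles 86, 22.9, 77.2, 98.3 and 65.1. Under the housekeeping shift these medians were 0.99, 0.63, 0.98, 1.21 and 0.89. Cardiac transcription factors had a median of 0.68 (percentile 99.88), led by Ankrd1 (5.20), Tbx20 (5.15) and Hand2 (2.24). The pluripotency median was -3.90 and the cell cycle median -1.57, both at percentile 0. Dissociation stress genes, which respond to tissue handling, had a median of 1.45 (percentile 100), and the epithelial median was -2.15 (percentile 0). Fatty acid oxidation and oxidative phosphorylation, main energy pathways of the adult heart, had medians of -0.09 (percentile 40.9) and -0.37 (percentile 6.2), or 0.74 and 0.47 under the housekeeping shift.

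Outside the lists, Ogn (7.62), the matrix gene Efemp1 (6.71), the Wnt antagonist Frzb (6.17), Il6 (interleukin 6, 5.78) and Col14a1 (5.45) were among the most strongly higher genes. There were 1802 genes at least 2-fold higher and 1940 lower of 13760, and 633 and 494 at least 4-fold. The housekeeping shift gave 5499 higher and 582 lower. Differences had an SD of 1.17, against 0.598 for probe sets of 1 gene.

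The adult and neonatal cardiomyocyte libraries were compared to ask how they differ from each other. The adult library had lower values for sarcomere, fetal isoform, imprinted growth and cell cycle genes, and higher values for macrophage genes. Of the 27 sarcomere genes, 8 were at least 2-fold lower and 0 higher, with a median of -0.41 (percentile 0). Nppa was lower, at -5.26, and so were Actc1 (-2.31), Des (-1.71), Tnnt2 (-1.54), Myh6 (-1.42) and Pln (-2.54). The sex-linked genes also differed between these libraries, Xist by -5.39 and Eif2s3y by 1.96.

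The fetal isoform median was -0.78 (percentile 0) and the adult isoform median -0.20 (percentile 1.07), the former being -0.20 over the 4 members on no other list. Of the imprinted growth genes, 4 of 11 were at least 2-fold lower, with a median of -0.91 (percentile 0), Peg3 at -3.70 and Mest at -1.96. Cell cycle genes had a median of -0.90 (percentile 0), the survivin gene Birc5 differing by -1.5. Macrophage and leukocyte genes had a median of 0.91 (percentile 100), with 6 of 15 at least 2-fold higher, among them Lyz2 (2.26), Mrc1 (1.66) and the complement genes C1qb (1.59) and C1qc (1.21). Stress genes had a median of 0.72 (percentile 100) and fibroblast genes one of 0.28 (percentile 99.88). Epicardial genes had a median of -0.64 (percentile 0.02), or -1.29 over the 6 members on no other list, and went both ways, the retinoic acid enzyme Aldh1a2 differing by 2.44 and Upk3b by -1.87. Medians of the ventricular, glycolysis, fatty acid oxidation and oxidative phosphorylation lists were -0.16, 0.22, 0.07 and -0.05 (percentiles 9.57, 99.58, 92.2 and 54.4).

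The genes most strongly higher in the adult than in the neonatal library included Cd200 (4.61), the chemokine Ccl6 (4.15), Arg1 (arginase 1, 3.78) and the macrophage elastase Mmp12 (3.40). Those most strongly lower, besides Xist and Nppa, included Nrk (-4.03), P-selectin (Selp, -3.86), Zim1 (-3.55) and the glypican Gpc3 (-3.37). Genes at least 2-fold higher numbered 332 and lower ones 385 of 13164, and 49 and 41 differed by at least 4-fold. With a filter at the 75th percentile, 203 genes were higher. Between probe sets of 1 gene the SD was 0.345, and that of all differences was 0.521.

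iPS cells differentiated with DMSO were compared with undifferentiated iPS cells. Pluripotency and cell cycle genes were lower, and endoderm, epithelial and dissociation stress genes were higher, together with part of the cardiac program. Cardiac troponin T (Tnnt2) differed by 2.97, the ventricular light chain Myl3 by 2.52, Actc1 by 1.86, Gata4 by 2.77 and Nppb, the B-type natriuretic peptide, by 4.0. The yolk sac and liver protein Afp differed by 5.96 and keratin 19 (Krt19) by 5.39. No untreated differentiated library was part of the set, so these differences cover differentiation and DMSO together.

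With DMSO, 20 of 23 pluripotency genes were at least 2-fold lower, with a median of -3.28 (percentile 0), Nanog at -7.31 and Utf1 at -6.46, while Klf4 was higher by 1.46. The cell cycle median was -2.17 (percentile 0), with Ccnd2, cyclin D2, higher by 2.84. In the sarcomere list 14 of 27 genes were higher and 0 lower, with a median of 1.04 (percentile 100). The ventricular median was 0.99 (percentile 99.98), the atrial one 0.44 (percentile 99.4) and that of cardiac transcription factors 0.85 (percentile 99.93), Hand1 being higher by 1.81. Of the atrial list 7 members were dim in both libraries, and the median of the others was 1.55. Fetal isoforms had a median of 1.03 and adult isoforms 0.24 (percentiles 99.97 and 95.1), and the fetal median was 0.28 over the 4 members on no other list. Endoderm genes had a median of 2.03 and epithelial genes 2.17, both at percentile 100, with the lipoprotein gene Apoa1 at 4.67 and keratin 18 (Krt18) at 4.61. Dissociation stress genes had a median of 1.79 (percentile 100), led by the transcription factors Atf3 (4.72) and Fosb (4.62). The fibroblast and smooth muscle medians were 1.02 and 0.82 (percentiles 99.94 and 99.4). In the ERBB list, with a median of 0.84 (percentile 99.9), the receptor Egfr was higher by 4.63 and the ligand Hbegf by 3.12, and Erbb2, Erbb3 and Erbb4 differed by 0.84, -0.06 and 0.33. Oxidative phosphorylation had a median of -0.64 (percentile 0.09; 0.41 under the housekeeping shift) and glycolysis -0.35 (percentile 6.87; 0.70 under that shift).

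Lists with medians nearer to 0 included mesendoderm (-0.02, percentile 39.4), pacemaker (-0.23, percentile 9.81), endothelial (-0.13, percentile 22.8), erythroid (-0.14, percentile 18.9), adipocyte (0.19, percentile 83.8) and skeletal muscle (0.02, percentile 49.9). Under the housekeeping shift these medians were 1.03, 0.82, 0.92, 0.91, 1.24 and 1.07. Calcium handling (0.13), fatty acid oxidation (-0.06), epicardial (-0.04) and macrophage (0.23) medians were also near 0. They were 1.18, 0.99, 1.00 and 1.28 under that shift, and the epicardial one was -0.86 over members passing the filter. Neural genes had a median of -0.46 (percentile 0.9; 0.59 under that shift), Sox1 at -2.96 and Otx2 at -2.61. The ERK feedback list had a median of 0.43 (percentile 94.7), or -0.30 over the 13 members on no other list, and the housekeeping genes one of -0.21 (percentile 20; 0.84 under that shift). Among the largest differences were those of Sprr1a, a component of the cornified envelope (8.03), Mal (6.62), Scel (6.42), Psca (6.34), the stomach gene Gkn2 (5.87) and involucrin (Ivl, 5.53). Counts were 1799 genes higher and 1829 lower of 13741, and 495 and 470 at 4-fold, against 8105 and 423 under the housekeeping shift. The SD of the differences was 1.09, and that of probe sets of 1 gene 0.553.

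**Figure D2:**
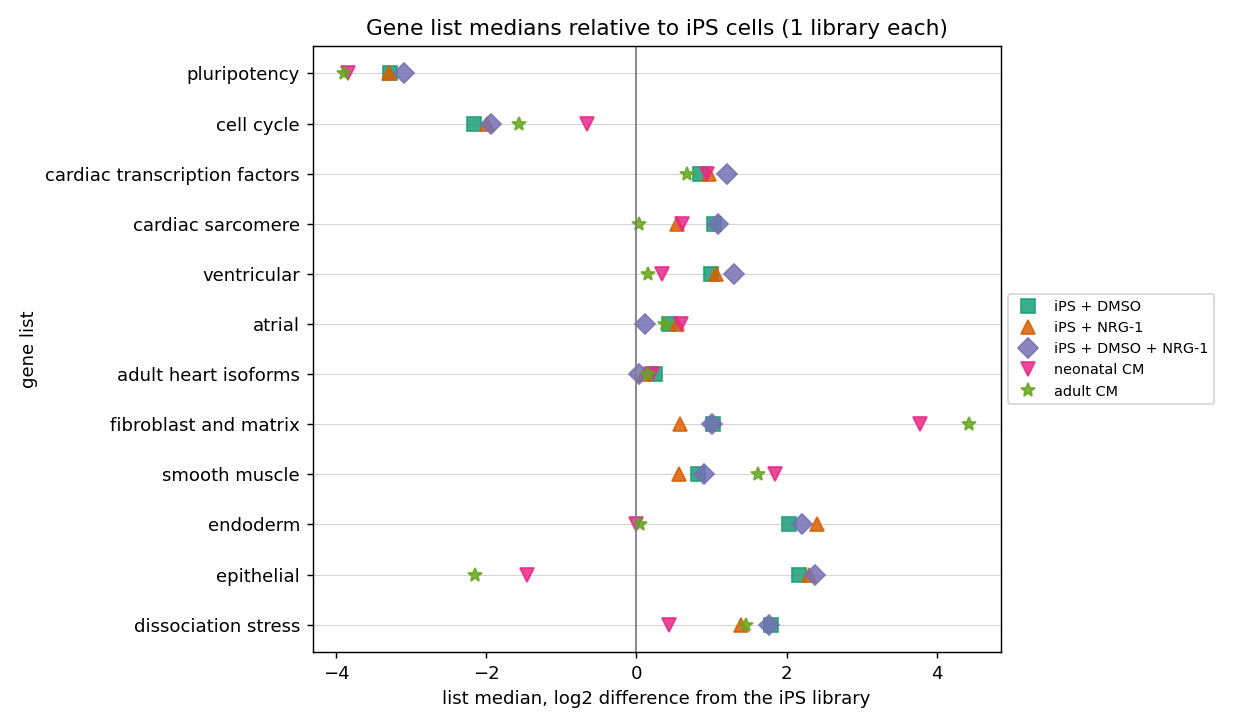
Each point is the median over a gene list (vertical axis) of the log2 difference (horizontal axis) between 1 library, named in the key, and the undifferentiated iPS library. The fibroblast and matrix medians of the neonatal and adult cardiomyocyte (CM) libraries lie at 3.77 and 4.44, while the endoderm and epithelial medians lie above 2 in the treated iPS libraries alone among those drawn.

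Cells differentiated with NRG-1 alone were compared with undifferentiated iPS cells in the same way. Myl3 was higher by 3.41, the myosin-binding protein Mybpc3 by 2.18, Tnnt2 by 2.15, Gata4 by 3.31 and Nppb by 3.66, while Myh6 and Actn2 differed by 0.11 and -0.41. The sarcomere median was 0.54 (percentile 99.98), with 9 genes at least 2-fold higher, and the ventricular median 1.06 (percentile 99.99). Afp was higher by 6.72, the retinol carrier Rbp4 by 5.08, Cyp26a1, which degrades retinoic acid, by 5.45 and the clotting factor F3 by 5.11. This comparison shares the iPS library with the others against iPS cells, so their differences are not independent.

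Pluripotency genes had a median of -3.30 (percentile 0) and cell cycle genes -2.00 (percentile 0) with NRG-1. Endoderm and epithelial medians were 2.41 and 2.30 (both percentile 100), with 12 of 15 and 7 of 11 genes at least 2-fold higher. Medians of the cardiac transcription factor, atrial, fetal isoform and adult isoform lists were 0.96, 0.54, 0.67 and 0.10 (percentiles 100, 99.87, 99.65 and 69.8). Over the 4 atrial members that passed the filter the median was 1.45, and Cited1, the only ventricular member on no other list, differed by 1.93. The fibroblast median was 0.58 (percentile 98.6), the stress median 1.4 (percentile 100) and the ERBB median 0.63 (percentile 99.65), Egfr being higher by 4.17. ERK feedback genes, which respond to growth factor signalling, had a median of -0.07 (percentile 46.4), or -0.88 over the 13 members on no other list and 0.40 under the housekeeping shift. Counts were 1554 genes higher and 1999 lower of 13763, and 407 and 509 at 4-fold, against 3077 and 1004 under the housekeeping shift. Differences had an SD of 1.07, and that of probe sets of 1 gene 0.601.

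Cells given DMSO and NRG-1 together were also compared with iPS cells. The sarcomere median was 1.09 and the ventricular median 1.30, both at percentile 100 (1.82 and 2.03 under the housekeeping shift, against 2.09 and 2.04 for DMSO alone), and 15 of 27 sarcomere genes were at least 2-fold higher. Tnnt2 was higher by 2.97, Myl3 by 2.81, the atrial light chain Myl7 by 2.06, Myh7 by 1.79 and the ryanodine receptor Ryr2 by 2.32. Cardiac transcription factors had a median of 1.20 (percentile 100), Gata4 at 3.11 and Hand1 at 1.41.

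Endoderm and epithelial medians were 2.21 and 2.37, the stress median 1.76, the pluripotency median -3.10 and the cell cycle median -1.94, the former group of 3 at percentile 100 and the others at percentile 0. The fetal isoform median was 1.14, the adult isoform median 0.03 and the atrial median 0.12 (percentiles 99.96, 62.6 and 80.7), the last being 1.71 over members that passed the filter and the fetal one 0.26 over the 4 members on no other list. Sprr1a (7.94), Gkn2 (6.42), Afp (6.05) and the retinoic acid hydroxylase Cyp26a1 (5.17) were among the most strongly higher genes. Counts were 1778 higher and 1793 lower of 13696, and 501 and 438 at 4-fold, against 4774 and 600 under the housekeeping shift. The SD of the differences was 1.08, and that of probe sets of 1 gene 0.562.

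**Figure D3:**
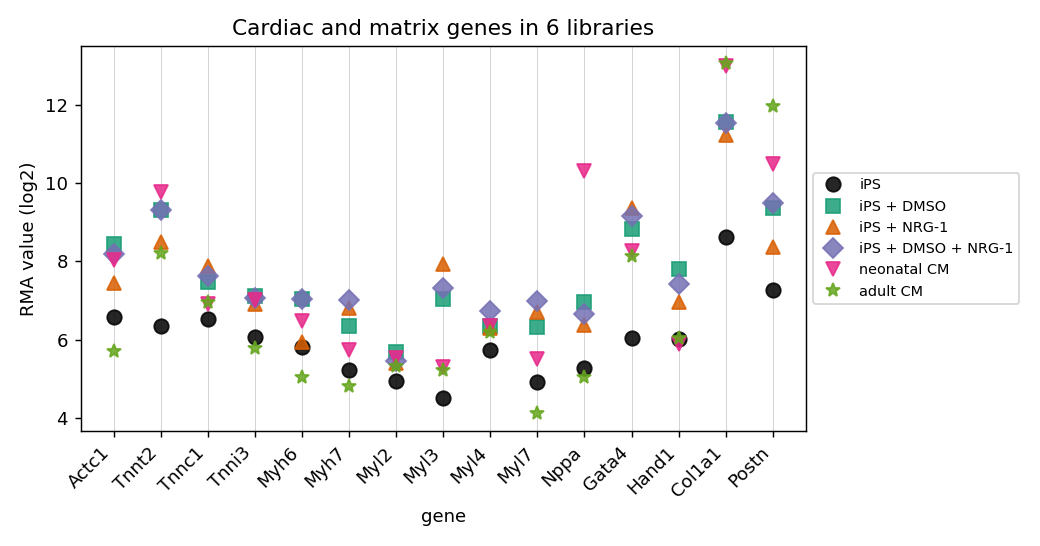
Each point is the RMA value (log2, vertical axis) of 1 cardiac or matrix gene (horizontal axis) in 1 of the 6 libraries, named in the key; values of different genes are not comparable with each other. Myl3 ranged from 4.52 in the iPS library to 7.93 with NRG-1, Nppa reached 10.31 in the neonatal cardiomyocyte (CM) library, and Postn reached 11.97 in the adult one.

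The NRG-1 and DMSO libraries were compared to set the growth factor against the solvent. Few list members were 2-fold apart. The sarcomere list had 1 higher and 4 lower genes, the endoderm list 2 and 1, and the pluripotency, fibroblast, fatty acid oxidation and epicardial lists had 2 lower genes each, while 8 other lists had 1 lower gene each. The transcription factor Osr1 (-2.80), keratin 4 (Krt4, -2.45), mesothelin (Msln, -2.01), uroplakin Upk1b (-2.10) and the growth factor Bmp4 (-1.95) were lower, and Apoa2 (1.4) and Spink1 (1.22) were higher. Of the 286 genes at least 2-fold apart among 13343, 238 (83.2%) were lower with NRG-1 and 48 higher.

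The fibroblast median was -0.48 (percentile 0), with Lox at -1.23 and Lum at -1.04, and the endoderm median 0.52 (percentile 100), which turned to -0.06 under the housekeeping shift. The sarcomere median was -0.20 (percentile 0.29) and the pluripotency median 0.12 (percentile 96.5; -0.45 under that shift), with Sox2 at -1.19 and Tdgf1 at -1.06. Actn2, Csrp3, Myh6 and Des differed by -1.24, -1.24, -1.11 and -1.0, and Mybpc3, Myl3 and Myh7 by 1.13, 0.89 and 0.45. The ventricular median was -0.04 (percentile 39.9) and the atrial one -0.03 (percentile 37). ERK feedback genes had a median of -0.33 (percentile 0.22), stress genes -0.27 (percentile 1.39), fetal isoforms -0.32 (percentile 0.6) and cell cycle genes 0.20 (percentile 99.98), the last being -0.38 under the housekeeping shift. That shift moved the median of all genes by -0.59. The median difference of the housekeeping genes themselves went from -0.18 to -0.76. A sign change under the shift is therefore not a change relative to those genes. The shift gave -0.78, -0.62, -0.60 and -0.91 for the sarcomere, ventricular, atrial and ERK feedback lists. The ERBB median was -0.14 (percentile 13.1), and the ligand Ereg differed by -1.76, or -2.39 on its brightest probe set. Among the most strongly higher genes were the noncoding RNA genes Rprl2 (1.60), Rny3 (1.5) and Rpph1 (1.24), and the 81 small nucleolar RNA genes had a median of 0.52, or -0.06 under the housekeeping shift. At 4-fold, 1 gene was higher and 10 were lower. The housekeeping shift gave 4 higher and 1876 lower at 2-fold. Differences had an SD of 0.377, and that of probe sets of 1 gene 0.305.

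Adding NRG-1 to DMSO, compared with DMSO alone, went with small differences. Of 13198 genes, 6 were at least 2-fold higher and 7 lower, and none reached 4-fold. Zfp97 (1.61) and Prl2a1 (1.18) were the highest of the genes that could be named, and Txlng (-1.10) and keratin 17 (Krt17, -1.03) were among the lower ones. Cell cycle genes had a median of 0.27 (percentile 100; -0.05 under the housekeeping shift), and the mitotic kinases Ttk and Haspin differed by 0.96 and 0.97. No gene of any of the 31 lists, those of the sarcomere and the ventricle included, reached 2-fold.

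The medians were 0.07 for the sarcomere (percentile 94.6), 0.13 for ventricular genes (percentile 96.8), -0.08 for atrial genes (percentile 24.2), 0.06 for cardiac transcription factors (percentile 86.3) and 0.13 for pluripotency genes (percentile 99.58). Under the housekeeping shift the sarcomere, ventricular, cardiac transcription factor and pluripotency medians were -0.25, -0.19, -0.26 and -0.19. Myh7 and Myl7 differed by 0.66 and 0.65. ERK feedback genes had a median of -0.08 (percentile 2.48). Without the filter on dim genes the counts were 22 higher and 28 lower, with the filter at the 75th percentile 0 and 1, and under the housekeeping shift 2 and 68. The SD of the differences was 0.211, close to the 0.197 between probe sets of 1 gene.

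The library with both agents was last compared with NRG-1 alone, which asks about DMSO in the presence of NRG-1. Here 144 genes were at least 2-fold higher and 39 lower of 13303, with 7 higher and 0 lower at 4-fold. Osr1 (2.13), Tmprss11e (2.20), Mal2 (2.07) and Upk1b (1.73) were higher, and Apoa2 (-1.32), Rbp4 (-1.31) and Rprl2 (-1.67) lower. The fibroblast median was 0.35 (percentile 99.92), the sarcomere median 0.29 (percentile 100), the ventricular median 0.18 (percentile 93.4), the endoderm median -0.46 (percentile 0) and the glycolysis median 0.34 (percentile 99.83). Actn2 differed by 1.38 and Myh6 by 1.10, both higher with DMSO present. Without the dim filter 65 genes were lower, and the housekeeping shift gave 390 higher and 11 lower. Differences had an SD of 0.344, and that of probe sets of 1 gene 0.299.

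The likeness of the libraries was described by Pearson's r across 14579 genes, which are not independent replicates. The 15 pairs were computed as a family. DMSO and DMSO plus NRG-1 were nearest to each other (r = 0.991), followed by NRG-1 and DMSO plus NRG-1 (0.978), DMSO and NRG-1 (0.974), and neonatal and adult cardiomyocytes (0.955). With the neonatal library, r was 0.843 for DMSO, 0.824 for NRG-1, 0.843 for both agents and 0.790 for undifferentiated iPS cells. With the adult library, the values were 0.838, 0.818, 0.835 and 0.761. These values depend on the filter, r between the neonatal and iPS libraries being 0.905 without it and 0.613 with a filter at the 75th percentile. Fibroblast and matrix medians were high in both cardiomyocyte libraries (3.77 and 4.44 over iPS cells). A higher r with them is therefore not by itself likeness to heart muscle. Sarcomere medians of DMSO, NRG-1 and both were 0.40, -0.01 and 0.28 minus the neonatal library, and 0.92, 0.39 and 0.99 minus the adult library. Differences that share no library were also correlated across genes. The difference NRG-1 minus DMSO had r = 0.01 with adult minus neonatal and r = -0.18 with neonatal minus iPS. For DMSO plus NRG-1 minus DMSO the values were -0.06 and -0.08, and for DMSO plus NRG-1 minus NRG-1 they were -0.05 and 0.15.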

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

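The items here come from probe sets that the comparisons did not use, and were chosen after the values were seen. Groups of 1 library allow no check for outlying samples. Among 17824 probe sets that name no single gene, 164 were at least 4-fold higher in each of the 3 treated iPS libraries than in the undifferentiated iPS library, and 147 of them have no gene name here. The largest such difference without a gene name was that of probe set 17221235, at least 4.88 in each treated library. Its values were 2.09 in the iPS library, 7.01 with DMSO, 7.72 with NRG-1, 6.97 with both, 4.65 in the neonatal library and 6.52 in the adult library.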

How the results depend on the processing

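The alternatives were planned, except that list medians and single genes under the housekeeping shift are given relative to the median of all genes, a choice made after the data were seen. No paired analysis was possible because each group has 1 library, and no library could be left out for the same reason. Cyclic loess altered the already equalised values little, and all counts, list medians and correlations stayed within 1.5-fold or 0.05 of those reported. They did so too with the brightest probe set, which can alter only the 1082 of 22180 genes with more than 1 probe set. With it, 18 of 1816 single-gene differences moved. Under neither did a single-gene difference at least 0.58 from 0 change sign, and sign changes of smaller ones were not counted. The cause of the changes below was not tested unless stated. No background values were used, so what dim signal limits could be judged only through the filters.

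The housekeeping shift moved the median of all genes from near 0 to 0.82 for neonatal minus iPS, 0.82 for adult minus iPS, 1.05, 0.47 and 0.71 for DMSO, NRG-1 and both minus iPS, -0.59 for NRG-1 minus DMSO, -0.33 for both minus DMSO, 0.26 for both minus NRG-1 and -0.03 for adult minus neonatal. By its construction it adds 1 number to each library, so it cannot alter a gap between genes or a correlation, and values relative to that median say nothing about stability. The median difference of the housekeeping genes went from -0.42 to 0.45 for neonatal, -0.31 to 0.52 for adult and -0.21 to 0.84 for DMSO minus iPS. For NRG-1 minus iPS it went from -0.37 to 0.11, for adult minus neonatal from 0.03 to 0, and for NRG-1 minus DMSO from -0.18 to -0.76. Counts and signs under the shift are therefore not, in general, relative to the differences of those genes. Taken as it stands, the shift moved 124 of 279 list medians and 801 of 1816 single-gene differences by 1.5-fold or more, and changed the sign of 75 and 258 of them. Of these, 4 list medians and 31 single-gene differences had been at least 0.58 from 0. These 4 list medians were oxidative phosphorylation with DMSO (-0.64 to 0.41) and with both agents (-0.61 to 0.12), cell cycle in the neonatal library (-0.66 to 0.21) and neural with both agents (-0.65 to 0.08), each minus iPS. Among the smaller medians that changed sign were endoderm (0.52 to -0.06) and cell cycle (0.20 to -0.38) for NRG-1 minus DMSO and cell cycle for both minus DMSO (0.27 to -0.05). It gave 5490 genes higher and 450 lower for neonatal minus iPS, 5499 and 582 for adult minus iPS, 8105 and 423 for DMSO, 3077 and 1004 for NRG-1, 4774 and 600 for both minus iPS, 4 and 1876 for NRG-1 minus DMSO, 2 and 68 for both minus DMSO, and 390 and 11 for both minus NRG-1.

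Without the dim filter, more genes being counted, both minus DMSO gave 22 higher and 28 lower and both minus NRG-1 gave 65 lower. At the 75th percentile filter, with fewer genes counted, both minus DMSO gave 0 higher and 1 lower and adult minus neonatal 203 higher. Over the 4 members on no other list, the fetal isoform median changed sign for neonatal minus iPS (-0.65) and was -0.20 for adult minus neonatal, 0.28 for DMSO and 0.26 for both minus iPS. Only Cited1 of the ventricular list is on no other list, so the ventricular values of 0.45 for adult minus neonatal, 1.93 for NRG-1 minus iPS and -0.43 for both minus NRG-1 are those of 1 gene and say nothing about the list. The ERK feedback median was -0.30, -0.88 and -0.70 for DMSO, NRG-1 and both minus iPS, and the epicardial median -1.29 for adult minus neonatal. Over members passing the filter, the atrial median was 1.55, 1.45 and 1.71 and the epicardial one -0.86, -0.79 and -0.64 for DMSO, NRG-1 and both minus iPS. The epicardial median was -1.10 for NRG-1 minus DMSO and the smooth muscle one 2.40 for adult minus iPS.

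Pearson's r moved with the range of genes. Without the filter, r with the iPS library was 0.908, 0.910, 0.911, 0.905 and 0.894 for DMSO, NRG-1, both, neonatal and adult, and 0.620, 0.642, 0.633, 0.613 and 0.569 at the 75th percentile. With the neonatal library it was 0.930, 0.921 and 0.929 for DMSO, NRG-1 and both without the filter and 0.707, 0.679 and 0.704 at the 75th percentile, and with the adult library 0.928, 0.921 and 0.927, and 0.704, 0.672 and 0.697.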

Other observations

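All of the sets and tests in this part were chosen after the results were seen. A set of 106 genes was at least 4-fold higher in each of the 3 treated iPS libraries than in any of the iPS, neonatal and adult libraries. It held 8 of the 53 measured keratin genes, 6 of the 15 endoderm genes and 6 of the 11 epithelial genes. The smallest of these differences was 5.87 for the stomach gene Gkn2, 5.83 for Psca, 5.73 for Afp, 4.79 for the skin channel Trpv3, 4.61 for Mal, 4.41 for Apoa1 and 4.37 for involucrin (Ivl). Keratin 8 (Krt8) was 11.83 with DMSO, 12.02 with NRG-1 and 11.77 with both, against 7.99 in iPS cells. Desmoplakin (Dsp), a junction protein, occludin (Ocln), a tight junction protein, and the fibrinogen chains Fgb and Fgg were also in the set, with smallest differences of 4.0, 3.91, 4.35 and 3.94.

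A second set of 140 genes was at least 4-fold higher in both cardiomyocyte libraries than in the iPS and treated libraries. Only 3 of the 27 sarcomere genes were at least 2-fold above iPS cells in the adult library, so few could enter this set. It held 8 of the 16 fibroblast and matrix genes and 0 of the 27 sarcomere genes. Its leading members were Esm1 (smallest difference 6.19), Lrrc32 (4.64), Piezo2 (4.43), Ogn (4.35), Calcrl (4.21), Vcam1 (4.09), Col14a1 (4.09), Rhoj (3.98) and the matrix Gla protein gene Mgp (3.82), and Pdgfrb (3.57), Prrx1 (3.51), Fap (3.51) and Ddr2 (3.51) were also members.

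In the adult cardiomyocyte library the fibroblast list stood 4.41 above the sarcomere list, each relative to iPS cells. Scaling that depends on intensity is argued against for the fibroblast list alone. Its median exceeded by 2.76 the highest of 10000 random lists matched on mean expression over the 6 libraries. The sarcomere median lay among its random lists (percentile 66.5), so this comparison says nothing about scaling there. Probe sets that fail to respond are argued against as the whole cause, since 13 of 25 sarcomere genes above the filter were at least 2-fold higher in another library. A candidate explanation is RNA mostly from fibroblast-like heart cells: the 12 adult isoforms not on the sarcomere list had a median of 0.16 over iPS, or 0.99 under the housekeeping shift, which moved the median of all genes by 0.82. A culture or sorting step before harvest, and a sample other than its label, stay open and were not tested. Macrophage and leukocyte genes were also higher in the adult library, with a median of 1.23 over iPS. The neonatal library had a fibroblast median of 3.77 and a sarcomere median of 0.61 over iPS, and the explanations were not tested for it.

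The adult library, labelled female, had Y-linked genes high and Xist low, and the neonatal library had both high. Cross-hybridisation with X-linked partner genes is argued against for Kdm5d and Uty in the adult library, since their partners Kdm5c and Kdm6a differed from iPS cells by -0.65 and -1.90 there. The partner of Eif2s3y was not analysed here, and general background was not tested. Male RNA in the adult library and RNA of both sexes in the neonatal library stay open, because the values of these genes are the pattern itself and no other value was used to test them.

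The NRG-1 library stood further from DMSO (286 genes 2-fold apart) than the library with both agents did (13 genes). A trend with gene length is argued against as the whole cause, since 240 of the 286 genes stayed 2-fold apart after the medians of 20 length bins, which ran from -0.11 to 0.16, were removed. The 81 small nucleolar RNA genes had a median of 0.52 for NRG-1 minus DMSO (percentile 100) and 0.03 for both agents minus DMSO (percentile 92.1). The former was -0.06 under the housekeeping shift, which moved the median of all genes by -0.59. The median difference of the housekeeping genes went from -0.18 to -0.76 under that shift. The median of the small nucleolar RNA genes also differed between other libraries, at -0.54 for neonatal minus iPS (percentile 0) and -0.39 for adult minus iPS (percentile 0.01). These values cannot tell different recovery of short RNA from different expression, so that explanation stays open. An effect of the absence of DMSO cannot be told apart from a feature of that culture or array, because only 1 library has NRG-1 without DMSO.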
